A study of Mus musculus with 2 samples.

How the data were processed

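Single-cell RNA-seq of FACS-sorted Oct4-GFP+ male germ cells from CD1 mouse embryos was deposited as 1 table per stage, E12.5 and E13.5, prepared with 10x v2 chemistry per the labels' protocols, a 3' assay that counts transcript ends by UMI. The deposited values are raw UMI counts per gene and barcode, not normalised. Cell Ranger, without a version, and the build mm10 (GRCm38) are named per the submitters' processing notes; the gene annotation they used is not given in the sources used here. In the values, each listed gene was present in at least 3 barcodes and each barcode had at least 201 genes. Of the genes, 15366 were listed for both libraries, 814 for E12.5 alone and 1064 for E13.5 alone; a gene listed in 1 table alone was given no ratio.

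Barcodes with 500 or more genes and under 10% mitochondrial UMIs were kept. At E12.5, 181 barcodes had fewer genes and 55 had 10% or more mitochondrial UMIs; at E13.5 these were 231 and 131. Kept barcodes of both libraries were log-normalised to 10000 UMIs and clustered together with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 principal components, 15 neighbours, resolution 0.5, no batch integration). Clusters were named from marker lists for germ, Sertoli, fetal Leydig, interstitial, endothelial, macrophage, erythroid, surface epithelial, mesonephric and mural cells. A cluster of 210 barcodes with a median of 1897 UMIs stayed unnamed and out of the germ-like class (116 barcodes at E12.5, 94 at E13.5). Within germ-like clusters, 3 barcodes at E12.5 with macrophage markers and 1 at E13.5 with erythroid markers at 0.5% or more of their UMIs were left out, a limit set after seeing the data. Scrublet, as in scanpy, called 61 doublets among kept barcodes at E12.5 and 26 at E13.5, with an expected rate of 0.06; they were kept in the main analysis and left out in an alternative.

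Counts of germ-like cells were summed per library (59673637 UMIs at E12.5, 58586487 at E13.5) and expressed as CPM. Ratios of E13.5 over E12.5 have exact conditional binomial (Clopper-Pearson) 95% intervals, levels exact Poisson intervals and shares of cells exact binomial intervals. With 1 library per stage, no p-value, standard error or count of changed genes was computed; at least 1.5-fold higher or lower is a class of size, and a gene with under 3 UMIs in a library was given no ratio. Gene lists (male germline, piRNA, Nodal, pluripotency, primordial germ cell, postmigratory germ cell, meiosis, retinoic acid, pro- and anti-apoptotic, death receptor, p53, S phase, G2/M, G1 regulators, DNA methylation, chromatin, imprinted, FGF, glycolysis, oxidative phosphorylation, heat shock and immediate early, endoplasmic reticulum and integrated stress response, Y-linked, mitochondrially encoded) were fixed before the data were examined, as were the designs and the alternatives unless said otherwise. A list's median over members at 10 CPM or more in either library was set against 10000 random lists of the same size matched in 20 expression bins, as a description of these libraries. Its counting interval came from 2000 Poisson redraws.

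Named genes were, by rule, the 10 largest and 10 smallest ratios among genes at 50 CPM or more in a library whose counting interval excluded 1, without predicted, haemoglobin, ribosomal protein and mitochondrially encoded genes; up to 2 members at each end of every list and its most abundant member; and Pou5f1, Sox2, Nanog, Nanos2, Dnmt3l, Dazl, Ddx4, Kit, Stra8, Bax, Trp53, Cdkn1b and Mki67. Other members at least 1.5-fold apart, and genes of the closing section, were named after their values were seen. Some list members are not reported here.

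For shares of cells with a UMI, each germ-like cell was thinned without replacement to 14500 UMIs, the 10th percentile of the shallower library rounded down to the nearest 500. Scores per cell were means of log1p thinned counts over list members at 1 CPM or more, without members that both lists hold, and rho was set against 10000 random lists. For sets of cells within a library, summed CPM was compared with the other cells, over genes at 10 CPM or more in those other cells; at first genes at that level in either set were used, and the rule was changed after its results had been seen because it let the small set pick the genes.

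Alternatives were TMM factors (edgeR 4.0.16), a denominator without mitochondrial, ribosomal protein and the 50 most abundant genes, all barcodes, a stricter filter (2000 genes, 5% mitochondrial), no Scrublet calls, equal weight per cell, other minimum levels for lists, resolution 1.0, a rule of 3 germ markers per cell, no cell filter, somatic barcodes kept, no clusters led by p53 targets or Stra8 (these last 2 chosen after seeing the data), thinning to 2000 UMIs or none, and a partial rho given cell cycle scores. On simulated counts with the depths of these libraries, 95.5% of intervals of 6695 unchanged genes and 94.5% of intervals of 200 genes changed by known folds held the true ratio, and all 67 genes changed 1.5-fold had an interval on the right side of 1. Of 100 simulated lists without a shift, 92% lay within the middle 95% of random lists; all 100 with 8 of 15 members shifted 1.5-fold lay above it. All 20 simulated pairs of lists with a shared factor lay above the middle 95%, and all 20 without one lay within it. These counts were Poisson draws around 1 shared profile, with no differences between genes or cells beyond those put in. Real genes and cells vary more, so these rates do not give the power of the comparisons in the data. Coordinates are from GENCODE M21 (GRCm38), where 16668 of 17244 symbols matched.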

Results

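Male germ cells of the mouse fetal testis were profiled by droplet single-cell RNA-seq at 2 stages of embryonic development, E12.5 and E13.5, with 1 library per stage. The cells came from CD1 embryos, an outbred strain, and were sorted by FACS for Oct4-GFP, a green fluorescent reporter of Pou5f1 (Oct4), which germ cells keep at these stages. The series concerns programmed death of germ cells in the fetal testis. The E12.5 table held 2847 barcodes, 16180 genes and 60383440 UMIs (molecules counted once by their molecular identifier), and the E13.5 table held 2992 barcodes, 16430 genes and 59842242 UMIs. With 1 library per stage there was no replicate check and no test: stage and library cannot be told apart, and each interval below covers counting error only.

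Germ-like cells made up nearly all barcodes that passed the cell filter. They were 2498 of 2621 barcodes at E12.5 (95.3%, 95% exact binomial interval 94.4 to 96.1%) and 2550 of 2670 at E13.5 (95.5%, 94.6 to 96.3%). These shares reflect the reporter gate and also the naming rule. Most other kept barcodes were in the unnamed low-UMI cluster, 116 at E12.5 and 94 at E13.5. That cluster's median germ marker share was 0.693% of UMIs, against 0.804% in germ-like cells. Its leading genes were nevertheless mostly haemoglobins, although only 3 of its 210 barcodes had 10% or more erythroid marker UMIs. Without barcodes carrying somatic markers, its leading genes were Tmsb4x, Ptn, Itm2a, Meg3 and Igfbp4, none of them a germ marker. The median depth of germ-like cells was 23481 UMIs and 4523.5 genes at E12.5, and 21856.5 UMIs and 4354 genes at E13.5. The median mitochondrial share was 3.86% at E12.5 and 4.68% at E13.5. Different clusters held the germ-like cells of the 2 libraries: clusters 0, 1 and 2 were mostly E12.5 and clusters 6, 7 and 8 mostly E13.5, so that stage, or library, was the main division among these cells. A Sertoli-like cluster held 4 barcodes at E12.5 and 25 at E13.5. Markers of Sertoli cells took 11.9 and 12.6 CPM (UMIs per 1e6 UMIs of summed germ-like cells) at E12.5 and E13.5, those of endothelial cells 34.6 and 21.4 CPM, those of surface epithelium 16.3 and 10.1 CPM, those of macrophages 1.69 and 0.580 CPM, and those of red blood cells 0.285 and 23.1 CPM.

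The first comparison asked how the transcripts of germ cells differed between the 2 stages. Nanos2, an RNA-binding protein that marks entry of germ cells into the male pathway, was 77.2-fold higher in the E13.5 library (counting interval 49.8 to 127), with 20 UMIs or 0.335 CPM at E12.5 and 1515 UMIs or 25.9 CPM at E13.5. This is a ratio of UMIs and not of expression, as the background check below was too coarse to separate the 20 UMIs at E12.5. The same check could not separate the Nanos2 share at E13.5 from background either. Rhox9 and Rhox6, X-linked homeobox genes of early germ cells, were 10.5-fold (10.1 to 10.9) and 9.41-fold (8.97 to 9.88) lower in the E13.5 library. The synaptonemal complex gene Sycp1 was 7.02-fold higher (6.66 to 7.40), and Pmaip1, which encodes the pro-apoptotic protein Noxa, was 5.45-fold higher (4.94 to 6.02). Most of the transcriptome was close between the libraries: of 7309 genes at 10 CPM or more in either library, 81.5% lay within 1.5-fold, the median log2 ratio of E13.5 over E12.5 was -0.022, and Spearman's rho across genes, which are not independent replicates, was 0.930.

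In GRCm38, Nanos2 lies on chromosome 7 (18987400 to 18988962, plus strand), Rhox6 and Rhox9 lie close together on chromosome X (37826910 to 37829857, plus strand, and 37899097 to 37901770, minus strand), Sycp1 lies on chromosome 3 (102818499 to 102936100, minus strand) and Pmaip1 on chromosome 18 (66458533 to 66465565, plus strand). All 5 are annotated as protein-coding genes. Rhox6 and Rhox9 are paralogs, so their separate counts are uncertain where reads could map to both.

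Among genes at 50 CPM or more in a library, the 10 highest ratios belonged to Ptgr1, Bnc2, Ipp, Sycp1, Uchl1, Cthrc1, C1ql1, Zmym3, Hesx1 and Cdkn1c. Ptgr1, a prostaglandin reductase, stood at 3.05 CPM at E12.5 and 63.9 CPM at E13.5. Bnc2, a zinc finger protein, stood at 4.51 and 53.6 CPM, and Uchl1, a ubiquitin hydrolase abundant in spermatogonia, was 6.72-fold higher (6.42 to 7.04). Cdkn1c, the imprinted inhibitor of cyclin-dependent kinases also called p57, was 4.02-fold higher (3.77 to 4.29). The 10 lowest ratios belonged to Rhox9, Rhox6, Plcd1, Pdlim4, Vamp8, BC048679, Sparc, Mfge8, Arpc1b and Crip1. Vamp8, a SNARE of vesicle fusion, was 7.58-fold lower in the E13.5 library (6.83 to 8.43), Sparc, a matricellular protein, 6.80-fold lower (6.40 to 7.23) and Arpc1b, a subunit of the Arp2/3 actin complex, 4.48-fold lower (4.30 to 4.66). Of these 20 genes, the log2 ratio of Sparc moved by 0.90 when all barcodes were summed without a filter, the only one to move by over 1.5-fold under any alternative.

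**Figure D1:**
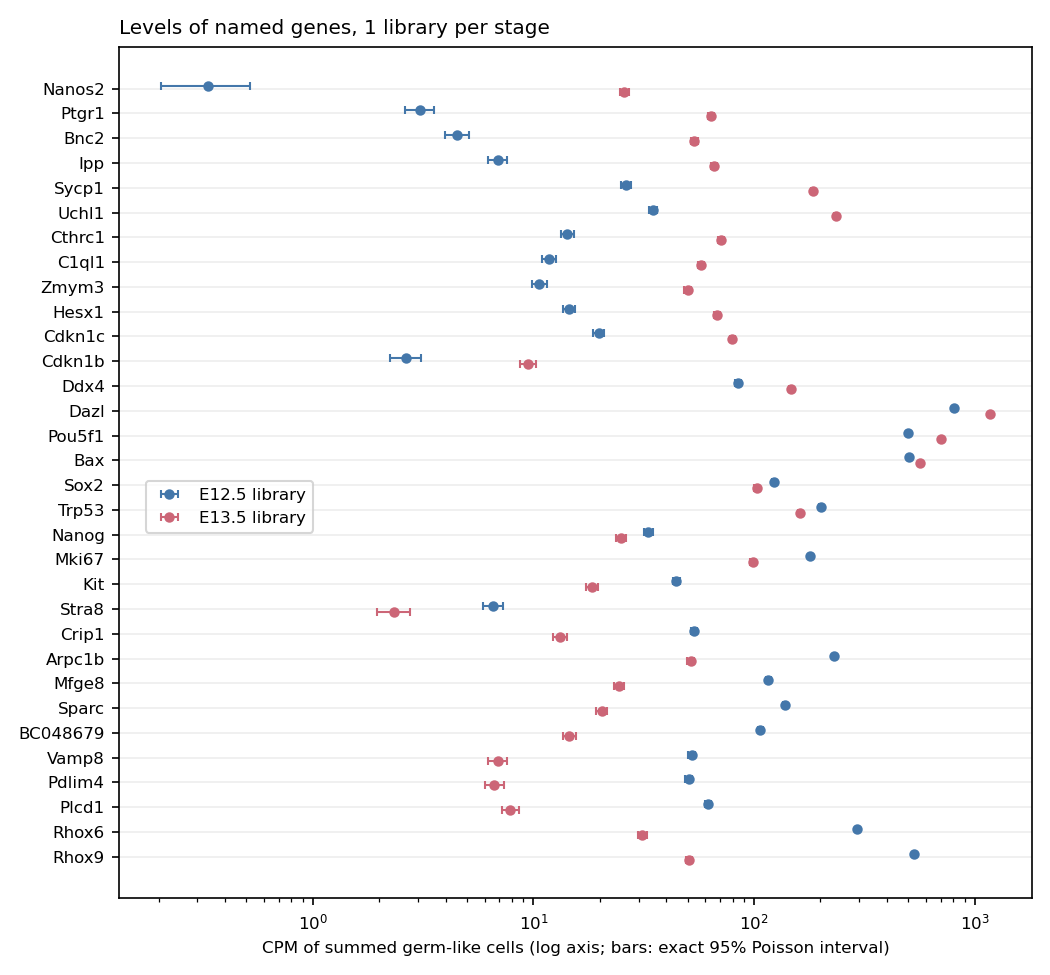
CPM of the summed germ-like cells of each library (log axis) for the genes named by size and those fixed in advance, with exact 95% Poisson intervals that cover counting error only. Nanos2 stood at 0.335 CPM in the E12.5 library and 25.9 CPM in the E13.5 library, and Rhox9 at 532 and 50.7 CPM.

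Pluripotency-associated genes were lower as a group in the E13.5 library, whereas Pou5f1 itself was not. None of the 18 measured members was 1.5-fold higher, 5 were at least 1.5-fold lower and 13 lay in between; the median log2 ratio was -0.42, below all 10000 random lists matched on expression. L1td1 was 3.15-fold lower (3.04 to 3.26) and Zfp42 (Rex1) 2.02-fold lower (1.93 to 2.13). Nanog stood at 33.2 and 24.9 CPM and Sox2 at 123 and 103 CPM at E12.5 and E13.5. Pou5f1, whose reporter defined the sort, stood at 500.2 CPM at E12.5 and 700.4 CPM at E13.5, 1.40-fold higher (1.38 to 1.42). Primordial germ cell genes split: 7 of 15 were at least 1.5-fold lower, among them Rhox6, Rhox9 and the stem cell factor receptor Kit (2.41-fold lower, 2.24 to 2.59), while Dppa3 (1.63-fold, 1.61 to 1.64) and Stk31 (2.35-fold, 2.27 to 2.42) were higher and 6 lay in between. The median of that list was -0.30, at percentile 0.39 of the random lists, and it turned to 0.049 when only members at 50 CPM or more were kept.

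Genes that germ cells switch on after they reach the gonad were higher as a group in the E13.5 library. Of 14 measured postmigratory germ cell genes, 7 were at least 1.5-fold higher and none was lower, with a median of 0.68, above all 10000 random lists. Ddx4, the germ cell RNA helicase, was 1.74-fold higher (1.69 to 1.81), Dazl, an RNA-binding regulator of germ cell fate, 1.46-fold higher (1.44 to 1.48) and Taf7l 6.32-fold higher (5.17 to 7.79). Of 13 genes of the piRNA pathway, which silences transposons, 6 were at least 1.5-fold higher and 7 lay in between. None was at least 1.5-fold lower (median 0.17, percentile 96.8, or 0.80 with no minimum level for 19 members). Gtsf1 at 4.39-fold (3.97 to 4.87) and Tdrd1 at 3.58-fold (3.03 to 4.25) led the list. Of 11 genes of meiotic entry and the chromosome axis, 4 were at least 1.5-fold higher: Sycp1, Sycp2 (3.34-fold, 2.97 to 3.76), Smc1b and Hormad2. Another 7 lay in between and none was at least 1.5-fold lower (median 0.35, percentile 99.9). Stra8, the retinoic acid target that starts meiosis in the fetal ovary, was scarce in both and lower at E13.5, with 6.57 and 2.34 CPM.

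The list for the male germline programme went both ways. Of its 10 measured members, 5 were at least 1.5-fold higher in the E13.5 library, namely Nanos2, Ddx25 (2.52-fold, 2.34 to 2.72), Bnc1, Mov10l1 and Lefty1. Another 3 were at least 1.5-fold lower, among them Lefty2 and Nodal. The median was 0.20 (percentile 92.7), or 0.79 with no minimum level and 0.71 at a minimum of 50 CPM, but the summed CPM was 510.2 at E12.5 and 492.3 at E13.5, so that median and sum differed in sign. Lefty2 and Nodal belong to Nodal signalling, whose own list had 2 of 8 members at least 1.5-fold higher and 3 lower (median -0.34, percentile 3.57). Nodal stood at 11.8 and 6.86 CPM and Lefty2 at 236 and 95.4 CPM, while Lefty1 stood at 93.2 and 152 CPM. These Lefty genes are paralogs and neighbours on chromosome 1, so their separate counts are uncertain where reads could map to both. Dnmt3l, a cofactor of male germline DNA methylation, was listed at E13.5 alone, with 15 UMIs or 0.256 CPM, and was given no ratio.

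Cell cycle genes were lower as groups in the E13.5 library, and some inhibitors were higher. Of 41 S phase genes, 14 were at least 1.5-fold lower, none was higher and 27 lay in between (median -0.48, below all random lists), with Rrm2 3.95-fold lower (3.74 to 4.17) and Cdc6 3.05-fold lower (2.73 to 3.41). Of 50 G2/M genes, 4 were at least 1.5-fold lower, 1 was higher and 45 lay in between (median -0.20, percentile 0.020); the proliferation marker Mki67 was 1.83-fold lower (1.77 to 1.89). Among CDK inhibitors, pocket proteins and G1 cyclins, 2 of 10 were higher, Cdkn1c and Ccnd1, and 2 were lower, Ccne1 (3.28-fold, 3.07 to 3.51) and Ccnd3 (2.55-fold, 2.46 to 2.66), with a median of 0.13 (percentile 88.0) and a summed ratio of 0.975, of the other sign. Cdkn1b (p27), which stood under 10 CPM, was 3.58-fold higher (2.99 to 4.30).

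Genes of the mitochondrial apoptosis pathway moved apart between the libraries. Of 14 measured pro-apoptotic genes, Pmaip1 and Bik (3.19-fold, 2.73 to 3.75) were at least 1.5-fold higher in the E13.5 library. Bad (2.92-fold, 2.70 to 3.17), Bcl2l11 (2.13-fold, 1.91 to 2.38), Bid and Casp6 were at least 1.5-fold lower, and 8 lay in between, among them the abundant effector Bax at 505 and 566 CPM. The median was -0.27, at percentile 2.25 of the random lists. Of 7 anti-apoptotic genes, Birc2 was at least 1.5-fold higher (17.4 and 26.1 CPM) and 6 lay within 1.5-fold; the median was 0.20 (percentile 92.8) and the summed ratio 0.935, of the other sign. None of the 11 death receptor genes reached 10 CPM. The list of p53 and its targets was lower, with 3 of 14 members at least 1.5-fold lower, Phlda3 (3.46-fold, 3.06 to 3.91), Tigar (102 and 48.7 CPM) and Ccng1, and Pmaip1 alone higher (median -0.33, percentile 0.22). Trp53 stood at 201 and 161 CPM.

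Signalling and metabolic lists also differed. FGF receptor signalling genes had the lowest median, -0.69 (percentile 0.35), with 4 of 6 at least 1.5-fold lower in the E13.5 library, such as Etv4 at 1.94-fold (1.84 to 2.05) and Spry1 at 1.82-fold (1.60 to 2.07). Of 17 glycolysis genes, 6 were at least 1.5-fold lower, led by Hk1 at 9.05-fold (7.79 to 10.6) and Pfkp at 5.65-fold (4.87 to 6.59). Another 11 lay in between and none was at least 1.5-fold higher (median -0.40, percentile 0.050). All 28 nuclear genes of oxidative phosphorylation lay within 1.5-fold (median -0.069, percentile 24.9), as did all 12 mitochondrially encoded genes, whose median was 0.16 (percentile 99.7). Imprinted genes had 3 of 11 higher, such as Mest at 1.89-fold (1.77 to 2.03), and 3 lower, such as Slc38a4 at 2.51-fold (2.22 to 2.84), with a median of 0.32 (percentile 98.5). All 8 DNA methylation genes (median -0.040, percentile 44.0) and all 17 repressive chromatin modifiers (median 0.034, percentile 78.1, with a summed ratio of 0.968, of the other sign) lay within 1.5-fold. Immediate early and heat shock genes had a median of -0.13 (percentile 28.6) and a summed ratio of 1.05, of the other sign, with Egr1 higher and Hspb1 lower, and genes of endoplasmic reticulum stress and the integrated stress response a median of -0.16 (percentile 12.6), with the serine synthesis genes Phgdh 3.85-fold higher (3.40 to 4.38) and Psat1 1.93-fold lower (1.83 to 2.03). Only 2 retinoic acid genes, Rara and Crabp1, and 2 Y-linked genes were at 10 CPM; the Y-linked Eif2s3y stood at 89.3 and 93.8 CPM.

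**Figure D2:**
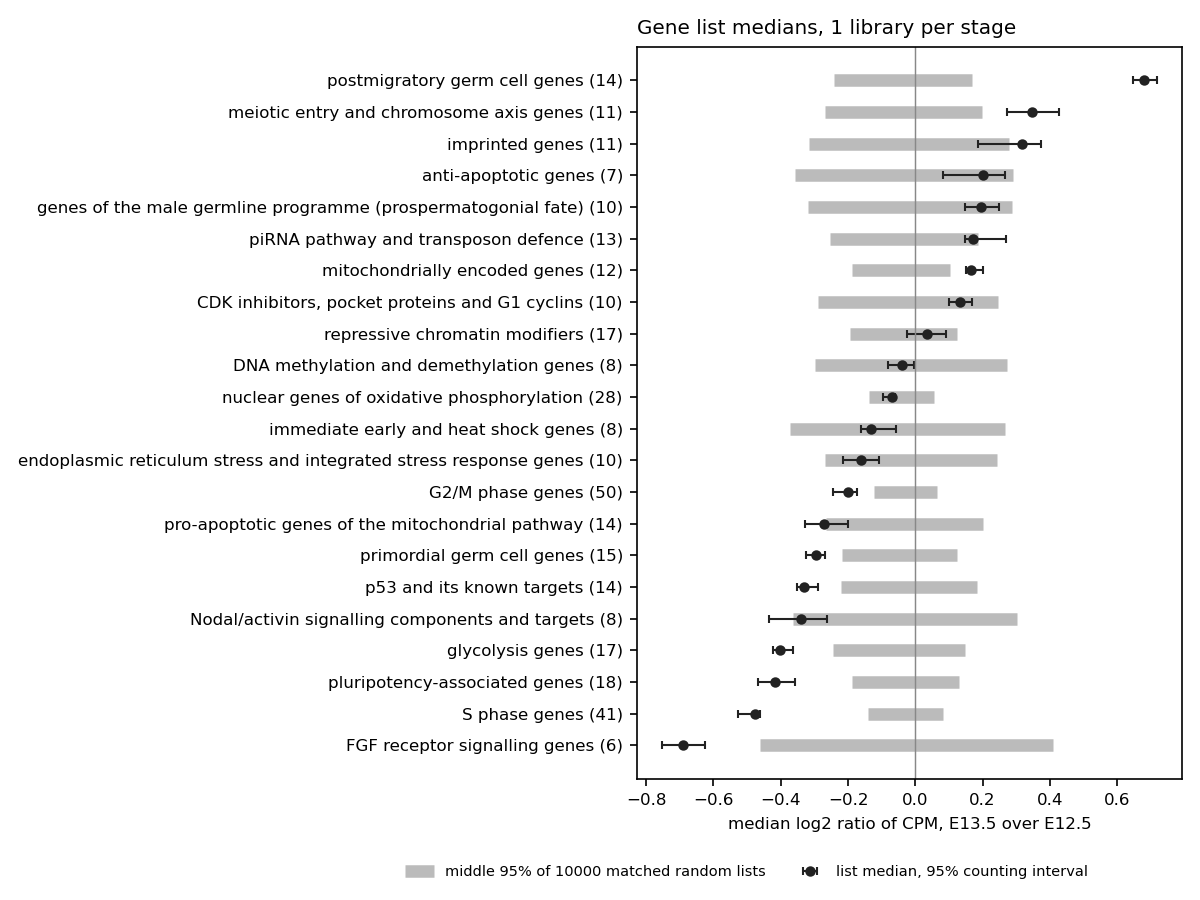
Median log2 ratio of CPM, E13.5 over E12.5, of each gene list (points, with 95% counting intervals; number of measured members in brackets) beside the middle 95% of 10000 random lists matched on expression (grey bars). Postmigratory germ cell genes lay at 0.68 and FGF receptor signalling genes at -0.69.

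The next comparison asked how many cells carried a transcript once each cell was thinned to 14500 UMIs, which left 2325 cells at E12.5 (173 shallower cells left out) and 2323 at E13.5 (227 left out). Nanos2 was seen in 12 cells at E12.5 (0.516%, 0.267 to 0.900%) and in 625 cells at E13.5 (26.9%, 25.1 to 28.8%); without thinning the shares were 0.761% and 34.5%. Sycp1 was seen in 27.2% (25.4 to 29.0%) and 78.9% (77.2 to 80.6%) of cells at E12.5 and E13.5, and Pmaip1 in 10.7% (9.44 to 12.0%) and 44.1% (42.0 to 46.1%). Rhox9 was seen in 99.1% (98.7 to 99.5%) and 32.3% (30.4 to 34.2%), Kit in 47.4% (45.3 to 49.4%) and 22.3% (20.6 to 24.0%), and Mki67 in 88.4% (87.1 to 89.7%) and 60.5% (58.5 to 62.5%). Stra8 was seen in 4.34% (3.55 to 5.25%) and 2.32% (1.75 to 3.02%). Without thinning, the shares at E12.5 and E13.5 were 37.1% and 86.0% for Sycp1, 16.3% and 56.0% for Pmaip1, 99.2% and 39.9% for Rhox9, 63.8% and 32.4% for Kit, 94.3% and 68.7% for Mki67, and 5.80% and 3.25% for Stra8.

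As background from free RNA, Sertoli-like cells were thinned to 2000 UMIs, since their median depth was 11418 UMIs. The 29 cells were pooled over both libraries, 4 from E12.5 and 25 from E13.5. The limits below therefore rest mostly on the E13.5 library and hardly bound background at E12.5. None of 29 carried Nanos2, Sycp1, Pmaip1, Kit or Stra8, which allows a share of up to 11.9% by the exact binomial interval, and 1 each carried Rhox9 and Mki67, which allows up to 17.8%. Ptgr1 was carried by 8 of 29 (27.6%), against 0.842% and 12.0% of germ-like cells at E12.5 and E13.5 at 2000 UMIs, so its level is not specific to germ cells. At 2000 UMIs the germ-like shares at E12.5 and E13.5 were under these limits for Nanos2 (0.0802% and 4.87%), Stra8 (1.28% and 0.549%), Pmaip1 (2.17% and 8.59%) and Kit (8.78% and 4.36%). They were also under them for Sycp1 at E12.5 (4.69%), Rhox9 at E13.5 (9.11%) and Mki67 at E13.5 (16.4%), so that this background could not be bounded closely for any of these shares. The few Nanos2 UMIs at E12.5 cannot be read as expression.

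**Figure D3:**
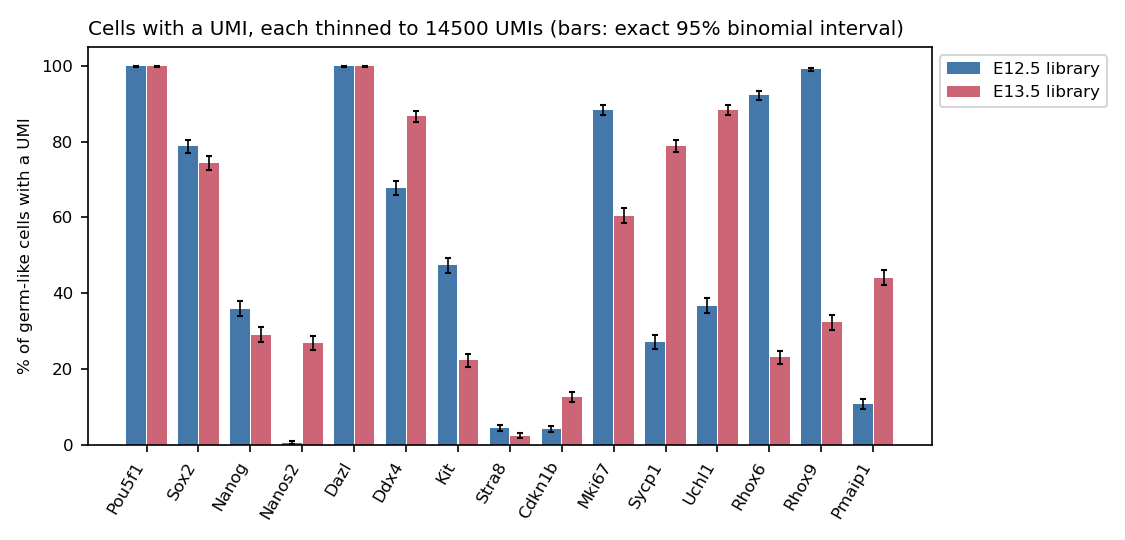
Percentage of germ-like cells with at least 1 UMI of each gene after thinning every cell to 14500 UMIs, per library, with exact 95% binomial intervals that cover counting error only. Nanos2 was seen in 0.516% of E12.5 cells and 26.9% of E13.5 cells, and Rhox9 in 99.1% and 32.3%.

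The last comparison asked whether pro-apoptotic transcripts went with other programmes from cell to cell within a library. At E12.5 the pro-apoptotic score had a Spearman's rho of -0.0274 with the male germline score across 2325 cells, at percentile 8.39 of 10000 random lists matched to the pro-apoptotic genes. At E13.5 this rho was 0.0980 across 2323 cells (percentile 93.5). The other rho values at E12.5 were 0.00909 with pluripotency genes (percentile 41.0), 0.0653 with S phase genes (percentile 86.7), -0.0690 with G2/M genes (percentile 6.83) and -0.00671 with p53 targets (percentile 40.0). At E13.5 they were 0.169 with pluripotency genes (percentile 96.5), 0.219 with S phase genes (percentile 93.7), 0.201 with G2/M genes (percentile 92.2) and 0.115 with p53 targets (percentile 95.2). All 10 values lay within the middle 95% of their random lists, so in thinned cells no relation beyond that of arbitrary genes of like level was detectable.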

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

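No test in this part was chosen only after its result was seen, but the rule for which genes enter the list of death-related transcripts was changed after a first result of a higher median, and the rule that members going both ways leave the question open was added after the result was seen. Outside the comparisons, barcodes with 10% or more mitochondrial UMIs were 55 of 2847 at E12.5 (1.93%, exact binomial interval 1.46 to 2.51%) and 131 of 2992 at E13.5 (4.38%, 3.67 to 5.17%). They are given here because no comparison used them; any count of more than a few barcodes would be. Their median depths were 3017 and 2565 UMIs.

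The nuclear RNA Malat1 took 3.19 times the share of non-mitochondrial UMIs in those E13.5 barcodes as in germ-like cells (counting interval 3.03 to 3.36), which is consistent with loss of cytoplasmic RNA from damaged cells. Whether transcripts of p53 targets and pro-apoptotic genes were raised in those barcodes stays open: the pooled lists had a median log2 ratio of 0.16, at percentile 32.8 of matched random lists, but of 24 measured genes 2 had a counting interval above 1, Pmaip1 (1.79-fold, 1.18 to 2.61) and Aifm1, and 3 had it below 1, Bax (0.735, 0.620 to 0.866), Cycs and Rps27l. Whether stage, cell death in the gonad or handling of the library made such barcodes more frequent at E13.5 cannot be told apart with 1 library per stage.

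Sertoli-like barcodes were 0.153% of kept barcodes at E12.5 (4 barcodes, 0.0416 to 0.390%) and 0.936% at E13.5 (25 barcodes, 0.607 to 1.38%). They are given here because the comparisons used them only as background from free RNA.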

How the results depend on the processing

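Leaving out the p53-led and Stra8-led clusters and keeping barcodes with somatic markers were alternatives chosen after seeing the data. Over 8 alternatives, 905 of 1000 log2 ratios of the 125 named genes stayed within their main counting interval; 4 had the other sign, Atp5b in 3 and mt-Co2 in 1 (log2 ratio of mt-Co2 -0.0113 under the stricter cell filter). Hspb1 and Sparc moved by over 1.5-fold when all barcodes were summed. Of 218 list medians, 175 stayed within their counting interval and 8 had the other sign, of which primordial germ cell genes (0.049 at 50 CPM) alone had stood outside the random lists. The minimum level mattered most: without it the piRNA median was 0.80 (19 members), the male germline one 0.79 (13 members) and the pro-apoptotic one -0.33, the first 2 moved by over 1.5-fold, and at 50 CPM they were 0.48 (8 members), 0.71 (3 members) and -0.10 (5 members), with meiotic genes at 0.10 (6 members); this follows from which members are measured. The stricter cell filter gave 0.49 for meiotic and -0.19 for pro-apoptotic genes. It moved the log2 ratio of Nanos2 by 0.42, its largest shift among named genes. This filter kept 2270 of 2498 germ-like cells at E12.5 but 1595 of 2550 at E13.5, so it acted unequally on the libraries. The cause of these shifts was not tested. Germ-like shares at E12.5 and E13.5 were 99.2% and 98.4% by markers per cell and 88.3% and 86.4% without a cell filter, which adds shallow barcodes. Nanos2 shares follow depth: 0.0802% and 4.87% at 2000 UMIs, and 34.5% at E13.5 unthinned. The rho values at E13.5 depended on the setting. Given cell cycle scores (for S phase and G2/M genes the other score alone), rho was 0.0544 with male germline genes, 0.0966 with pluripotency genes, 0.143 with S phase genes, 0.113 with G2/M genes and 0.0481 with p53 targets. Without thinning these were 0.160, 0.251, 0.298, 0.307 and 0.165, each above the upper end of the random lists' middle 95% on thinned cells (0.123, 0.179, 0.276, 0.280 and 0.130); random lists were not run without thinning, so whether those values exceed chance is not known. At E12.5 no rho left the range of the thinned random lists in any of these settings, nor without doublet calls or the p53-led cluster.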

Other observations

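The sets of cells, their UMI limits and the tests in this part were chosen after results were seen, apart from the tests of heat shock genes, of macrophage markers per Tmsb4x UMI and of the meiotic list in the cluster; for these, the rule for measured genes, the reading of lists whose members go both ways and the need for a counting interval on the Tmsb4x ratio were set after first results, and the interval turned a reading in favour of macrophage RNA into an undecided one. The p53 test was first run on medians and then on summed UMIs. The test of macrophage RNA for Stra8 replaced another whose outcome was nearly fixed, and its own outcome was largely set by how the cells were picked. Within the E13.5 library alone, where stage and library are fixed, 210 cells had 2 or more Nanos2 UMIs after thinning, 415 had 1 and 1698 had none, with median mitochondrial shares of 5.02% in the first set and 4.57% in the last. The median depths of those sets were 19940 and 22993.5 UMIs, and their profiles were summed without thinning. Cells with 2 or more had lower cell cycle transcripts than cells with none. Of 38 S phase genes, 24 were at least 1.5-fold lower and none was at least 1.5-fold higher (median log2 ratio -0.70, below all 10000 matched random lists). Of 50 G2/M genes, 25 were at least 1.5-fold lower (median -0.58). Nodal genes were lower (median -1.32, 4 of 7 at least 1.5-fold lower), Lefty1 at a ratio of 0.224 (0.193 to 0.259), and so were Rhox9 at 0.0862 (0.0556 to 0.128) and primordial germ cell genes (median -0.54). The male germline list, which shares members with the Nodal list, was also lower (median -0.68, below all random lists); Nanos2 itself is not among its 8 measured members. The piRNA (median 0.31) and postmigratory germ cell genes (0.28) were higher, above all random lists, and Taf7l was 3.76-fold higher (3.05 to 4.62). Pro-apoptotic genes had a median of -0.27 (percentile 0.97). Cells with 1 Nanos2 UMI lay between, with S phase genes at -0.39 and Nodal genes at -0.57.

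A small cluster, 25 cells at E12.5 and 3 at E13.5, was led by p53 targets such as Plk2, Phlda3 and Cdkn1a. Over 20 target genes, 47 of 2325 thinned cells at E12.5 (2.02%, exact binomial interval 1.49 to 2.68%) and 5 of 2323 at E13.5 (0.215%, 0.0699 to 0.502%) had 20 or more target UMIs, against a median of 6 in both libraries. With a limit of 15 UMIs these were 108 and 27 cells, and with 30 UMIs 18 and 2; 20 and 6 cells lay within 2 UMIs of the limit of 20. In the cluster's E12.5 cells, pluripotency genes were lower than in other germ-like cells (median -0.71, below all random lists), G2/M genes also (-0.56), S phase genes were slightly higher (0.11, percentile 99.9), and pro-apoptotic genes had a median of 0.15 (percentile 96.1). That median leaves out members under 10 CPM in the other cells, among them the p53 targets Bbc3, which encodes Puma and was 9.15-fold higher (6.29 to 12.9), and Apaf1, 5.27-fold higher (3.35 to 7.94). Not every member left out was clearly higher: Pmaip1 was at a ratio of 1.40 (0.511 to 3.07), and Bik had 0 UMIs in these cells.

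Against doublets as the source of these cells, the cluster's median depth was 0.893 times that of other germ-like cells. Stress of dissociation or sorting stays open: immediate early and heat shock genes had a median ratio of 1.08, but over 7 members that went both ways, with Fos 3.67-fold (2.22 to 5.72) and Ier2 1.49-fold higher (1.14 to 1.92) and Hspa8 at 0.848 (0.806 to 0.891). Activation of p53 targets in a few cells may account for it: E12.5 cells ranked in the top 1% by part of the p53 list had 1.89 times the UMIs of the other part of the list seen in the remaining cells, or 3.11 times with the parts exchanged, each above all random lists. Of the 23 top cells at E12.5, 10 were in the cluster in the first ranking and 17 in the other. The same ratios at E13.5 were 1.66 and 1.36 (percentiles 100 and 99.84), with 2 of 23 top cells in the cluster each way. Most top cells at E13.5 thus lay outside the cluster. The ratios were not computed without the cluster's cells, so a joint rise of p53 targets outside it was not tested. Activation of p53 targets remains a hypothesis for the cluster, as it was found and tested on the same cells. Damage or stress before or during the sort stays open.

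A second set at resolution 1.0, with 84 germ-like cells at E12.5, carried Stra8 at 103 CPM against 3.98 CPM in the others. Id1, a BMP target, was 10.7-fold higher there (9.08 to 12.6). Both genes were among those that led the cluster, so these ratios partly reflect how the set was found. Stra8 was seen in 40 of the 84 cells, which held 161 of the 392 Stra8 UMIs of E12.5 germ-like cells. Nodal (median -1.40) and male germline genes (-1.11) were lower there than in other E12.5 cells, below all random lists. The set was also shallower, with a median of 18688.5 UMIs against 23602.5 in the others. Its median mitochondrial share was 3.16% against 3.89%. Germ cells of female embryos are argued against by Y-linked transcripts, at 0.963 times the level of other cells (0.822 to 1.12). For macrophage RNA as the source of Stra8, the 3 barcodes left out for macrophage markers held 364 marker UMIs and 0 of Stra8. The set held 5 and 161 (upper limit of the odds ratio 0.000476). This odds ratio was largely set by how the cells were picked: the barcodes for macrophage markers, the set as a cluster led by Stra8. It cannot decide the question, and shows only that no Stra8 UMI was seen in those 3 barcodes. Tmsb4x, which led this cluster only while those barcodes were in it, was not clearly higher in the set (1.35-fold, 0.842 to 2.07); its marker UMIs per Tmsb4x UMI, at 0.647 times those of the barcodes (0.209 to 1.52), rest on 5 UMIs, so that macrophage RNA as its source cannot be told apart from expression by these cells. A wider meiotic programme may be present: meiotic genes without Stra8 had a median of 0.39 (percentile 99.98), although only 1 of 9 was at least 1.5-fold higher. Other lists were about as far out in the cluster. Primordial germ cell genes were at 0.32 (percentile 100) and imprinted genes at 0.43 (percentile 99.87). Glycolysis genes were at -0.42 (percentile 0.01) and mitochondrially encoded genes at -0.35 (percentile 0.23). The shift was thus not particular to meiotic genes. Among 50 cells picked by 2 or more Stra8 UMIs instead, the meiotic median was 0.77 and 5 of 9 were at least 1.5-fold higher. Rec8, a meiotic cohesin under 10 CPM in the other cells and so outside these 9, was 8.78-fold higher (5.75 to 13.0). In the cluster Rec8 was 5.51-fold higher (3.59 to 8.16). Nodal genes were not lower in the 50 cells (0.091), nor were male germline genes (0.21, percentile 95.3). Primordial germ cell genes were at -0.035 there (percentile 56.8), so the sets differ in these lists.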
